A study of Mus musculus with 7 samples.

How the data were processed

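Gastruloids are aggregates of mouse embryonic stem cells that pattern themselves into axial tissues in culture. Per the labels' protocols, cells of the SBR line, a Sox1 and Brachyury reporter line on the CGR8 background of strain 129, were kept in serum medium with 0.1 µg/ml LIF, 3 µM of the Wnt agonist CHIR99021 and 1 µM of an inhibitor. Aggregates of 300 cells were then grown in N2B27 medium and received a pulse of 3 µM CHIR99021 from 48 to 72 h after seeding. At each time 24 to 240 gastruloids were pooled and dissociated, 12000 live cells were sorted, and the cells were run on the 10x Genomics 3' version 3 chemistry, per the labels' protocols. The sort on live cells can set which cells entered the libraries.

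The authors deposited estimated counts of spliced UMIs and estimated counts of unspliced UMIs per gene and cell, not normalized, for 54298 genes and 33964 cells. Per the submitters' processing notes, Salmon 1.1.0 and alevin 1.1.0 were used with genome build GRCm38 and R 4.0.2. The role of each tool, the filter on cells and any removal of doublets were not given in the sources used here. Of the spliced entries 84.4% were whole numbers, and of the unspliced entries 65.5%. The remaining entries were fractions, as arise when a UMI is shared between genes. The authors also deposited log2 values, each equal to log2 of the spliced count divided by a factor per cell, plus 1. This was checked in every cell by recovering the factor from the values, and how the factor was made was not given in the sources used here. The authors' annotation gave 1 of 18 cell type names to each cell, except 120 cells with no name. How the names were assigned was not given in the sources used here, and names of this kind rest on expression.

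Libraries were grouped by the time point in the labels. Times of 24, 36, 48, 60 and 72 h had 1 library each, and 84 h had 2. Spliced UMIs were summed per library over all deposited cells and expressed as CPM of the library's spliced total. No test between times was run and no p-value was computed, since only 84 h had more than 1 library, which left 1 residual degree of freedom. Genes were instead counted by a fixed rule of size. It was set before the data were examined, as were the gene lists, the rule for named genes and most alternatives. A gene counted when its CPM was at least 10 at 1 of the times compared and the ratio of CPM plus 1 was at least 2-fold either way. For 84 h the mean of both libraries was used, and both had to pass in the same direction. The same rule applied between the 84 h libraries gave the background. The main comparisons were 24 h with 48 h, 48 h with 72 h and 72 h with 84 h, and each step of 12 h was counted too. Log2 ratios are on the scale of CPM plus 1, which understates differences of genes with low CPM.

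The text names up to 12 genes per direction with the largest log2 ratio in each main comparison and up to 5 per direction in each 12 h step, leaving out predicted genes, mitochondrially encoded genes and ribosomal protein genes. It also names up to 4 members with the largest absolute log2 ratio of each fixed list with at least 3 measured members, and T, Sox2, Sox1, Pou5f1 and Nanog in every library. The values of some genes that this rule picks are not reported here. Genes named outside this rule were chosen after their values were seen: those of lists with fewer than 3 measured members, those named within annotated cell types, the further list members at 84 h in cells annotated Epiblast, and those in the closing observations. The 30 fixed lists were naive pluripotency, shared pluripotency, primed epiblast, 2-cell-like, primitive streak, nascent and cardiac mesoderm, presomitic mesoderm, caudal epiblast and neuromesodermal, definitive endoderm, neural ectoderm, extraembryonic endoderm, primordial germ cell, endothelial and blood, fibroblast, Wnt targets, Nodal targets, BMP targets, FGF and ERK targets, Notch pathway, retinoic acid pathway, epithelial, mesenchymal, glycolysis and hypoxia, cholesterol synthesis, p53 targets, integrated stress response, dissociation and immediate early, S phase, G2/M phase and anterior Hox. Some genes stand in more than 1 list, such as Hoxb1, Nodal, Tdgf1, Snai1 and Dll1. For each list with at least 3 measured members, the median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. Positions below, within or above the middle 95% of the random lists describe these libraries and are not p-values.

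To compare shares of cells with a UMI of a gene, each cell was thinned to 5000 spliced UMIs by drawing without replacement from its counts rounded to the nearest whole number (0.5 to 0), and shallower cells were left out. Shares carry exact Clopper-Pearson 95% intervals and sums carry exact Poisson 95% intervals. These cover counting error only, and a count of 0 was given the limit that 3 counts allow. Cell types came from the authors' annotation, which took the place of clusters made here by a choice made before the data were examined. The streak and mesodermal class summed the names Primitive Streak, Anterior Primitive Streak, Caudal epiblast and those of mesoderm. Within an annotated type, UMIs were summed where a library held at least 10 cells of it. The unspliced share was unspliced over spliced plus unspliced UMIs.

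The alternatives chosen beforehand were TMM scaling (edgeR 4.0.16, used for TMM alone), spliced plus unspliced UMIs, a stricter filter on cells (at least 2000 genes and at most 10% of spliced UMIs from mitochondrial genes), the mean of each cell's CPM, removal of Scrublet doublets, CPM floors of 5 and 20, a pseudocount of 5, other thinning depths, other clustering settings, and leaving out each 84 h library. The authors' per-cell factors, removal of the 5% of cells with the highest Scrublet score, clusters named by the fixed markers in place of the annotation, and rounding fractions up or down at random in proportion for the shares of cells were added after seeing the data. Scrublet, run in scanpy 1.11.5 per library with an expected rate of 5%, marked 0.0756% to 0.342% of cells. No cell was removed from the main results on these calls. Whether the caller missed doublets or few were left in the deposited cells was not tested. Clusters were made with the Leiden algorithm (leidenalg 0.10.2, resolution 1) on 30 principal components of 2000 variable genes with 15 neighbours per cell. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3.

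The size rule and the list positions were tested on simulated Poisson counts drawn from the real means of the earlier time and the library sizes. Of the genes with a CPM of at least 20 at that time, 200 picked at random were altered. For 24 h with 48 h, 48 h with 72 h and 72 h with 84 h alike, 67 of 67 genes made 3-fold different and 66 of 66 made 6-fold different were called, and 0 of 67 made 1.5-fold different. No unaltered gene was called, out of 7104, 7183 and 7492 in that order. The simulated counts held counting error but no variation between libraries, so this does not give the rate of false calls between real libraries. Of 200 lists of 10 unaltered genes, 2.5%, 3% and 5.5% fell outside the middle 95%. Thinning of 4000 simulated cells gave a UMI in 63.8% of cells, against 63.2% expected.

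Depth per library was 38.1 M to 93.5 M spliced UMIs, so that a CPM of 10 stood for 381 to 935 UMIs. Of the gene identifiers listed, 54063 were found in the reference annotation of GRCm38. Only 4 of 80 protein-coding ribosomal protein genes had a row in the tables used here, while 299 copies with pseudogene names had one and held 2.47% to 3.39% of spliced UMIs. UMIs of the parent genes may have been counted on such copies, so ribosomal protein genes and copies are reported as uncertain. The same holds for Sprr2a1, Sprr2a2 and Sprr2a3, whose near-identical sequences can share UMIs.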

Results

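Single-cell transcriptomes were collected from gastruloids over 6 time points from 24 to 84 h after seeding, to follow how a uniform aggregate of stem cells comes to hold different cell types. The 7 libraries held 33964 cells: 4392 at 24 h, 7547 at 36 h, 5288 at 48 h, 4537 at 60 h, 4719 at 72 h, and 3184 and 4297 in replicates 1 and 2 of 84 h. Spliced UMIs came to 58.4 M, 93.5 M, 71.3 M, 51.1 M and 66.9 M at 24, 36, 48, 60 and 72 h, and to 38.1 M and 47.4 M in the 84 h libraries. Median spliced UMIs per cell ran from 10564 in 84 h replicate 2 to 13672 at 72 h. Mitochondrial genes took 4.07% to 4.57% of spliced UMIs. Each time before 84 h had 1 library, so differences between times had no replicate check there.

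Most genes differed little between the 84 h libraries. The log2 ratios between them had an SD of 0.10 over 7842 measured genes, and 99% of the genes lay within 0.26. By the size rule 14 genes were higher in replicate 2 and 0 were higher in replicate 1. All 14 were copies of ribosomal protein genes or predicted genes, among them Rpl9-ps6 at 28.0 and 86.1 CPM and Rpl17-ps3 at 163 and 360 CPM in replicates 1 and 2. Per gene, the median chi-square between the libraries was 0.630, against 0.472 to 0.507 between random parts of 1 library and 3.48 between 72 h and 84 h replicate 1. The mean was 5.07, against 1.19 to 1.45 and 39.0, so some genes differed by far more than random parts did. The labels do not say whether the 84 h pools came from separate cultures, so the SD between them may be technical.

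Before the pulse, from 24 to 48 h, most measured naive pluripotency genes were lower, and some epithelial and primed epiblast genes were higher. Of 10 measured naive pluripotency genes, 9 were lower at 48 h and 0 higher. Nr0b1, a nuclear receptor of naive stem cells, stood at 310 CPM at 24 h and 22.0 at 48 h, and Zfp42, also known as Rex1, at 394 and 36.0. Tcl1 was at 31.2 and 2.34 CPM, and the pluripotency regulator Esrrb at 10.7 and 1.14. The median log2 ratio of the list was −1.95, below 95% of matched random lists. Pou5f1, the core pluripotency factor, was at 1341, 1196 and 1102 CPM at 24, 36 and 48 h.

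Epithelial genes were higher at 48 h in 4 of 8 measured members, with a list median of 1.16 above the matched lists. The tight junction gene Cldn7 was the gene with the largest ratio of the comparison, at 2.31 CPM at 24 h and 73.0 at 48 h. Cldn6 was at 13.7 and 66.9, and the keratins Krt18 and Krt8 were at 22.6 and 103 and at 16.9 and 52.3. Of 12 primed epiblast genes 3 were higher, Car4 (11.0 and 32.0 CPM), the growth factor gene Fgf5 (74.2 and 163) and the DNA methyltransferase Dnmt3b (642 and 1361), with a median of 0.34. No shared pluripotency gene of 10 passed the size rule, although the list median was −0.65, and L1td1 was at 785 and 428 CPM. Other genes with the largest higher ratios were Cda, Psmb8, Kif1a, Rab25, Zfp36l3, Lbh, Tox3, Espn, Stk39, Crym and Fgf8, the last a ligand at 2.31 and 20.1 CPM. Among the largest lower ratios were Atp1a4 (21.0 and 0.0981 CPM), Mymx, a factor of myoblast fusion (128 and 5.48), H2-M5, Jam2, Myo1f, Eprn, Phf11d, Notum, Lgals3 and Dusp27.

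Metabolic and stress lists also stood apart between 24 and 48 h. Of 10 glycolysis and hypoxia genes 2 were higher and 1 lower, with a median of 0.43: the glucose transporter Slc2a1 was at 145 and 594 CPM and the lactate dehydrogenase Ldha at 980 and 2578, while the transporter Slc2a3 was at 39.5 and 16.0. Of 10 p53 targets 3 were higher, Pmaip1, Phlda3 and Ccng1 (133 and 284 CPM), with a median of 0.71. Both medians lay above the matched lists. Of 5 dissociation and immediate early genes Btg2 alone passed, being higher, and the median was 0.74, but it was −0.21 when unspliced UMIs were added. FGF and ERK targets had 1 of 9 lower, Etv4, with a median of −0.32, and Wnt targets had 1 of 4 lower, Notum, which encodes a Wnt deacylase (24.6 and 1.16 CPM), with a median of −0.52. Integrated stress response genes had a median of −0.31 over 6, although the member that passed, Ddit4, was higher (19.4 and 67.3 CPM). Of 3 extraembryonic endoderm genes Lamb1 was higher and Sparc lower, with a median of −0.64, and 0 of 10 S phase genes passed, with a median of −0.23. The medians of these last 5 lists lay below the matched lists.

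Within the range of matched lists from 24 to 48 h lay Nodal targets (0 of 7 past the size rule, median −0.26), BMP targets (0 of 5, 0.13), the Notch pathway (Hes1 higher among 3, 0.06), the retinoic acid pathway (Crabp2 higher among 3, 0.14), cholesterol synthesis (0 of 12, 0.10), G2/M phase (0 of 10, −0.10) and primordial germ cell genes (Prdm1 lower among 3, −0.29). Lists with fewer than 3 measured genes had no median, and their genes are named after their values were seen. In these, Fgf8 was higher of 2 primitive streak genes, Krt7 of 2 definitive endoderm genes, Sox3 and Nes of 2 neural ectoderm genes, and Thy1 of 1 fibroblast gene. Lower were Cldn5 and Pecam1 of 2 endothelial and blood genes and Fn1 of 2 mesenchymal genes. None of 1 nascent and cardiac mesoderm gene and 2 presomitic mesoderm genes passed, and 0 genes of the 2-cell-like, caudal epiblast and neuromesodermal and anterior Hox lists were measured. The 2-cell-like list also had 0 measured members at the later times.

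Over all genes measured, 364 of 7842 were higher and 368 lower at 48 h than at 24 h, against 14 and 0 between the 84 h libraries. In the first 12 h, from 24 to 36 h, 131 genes were higher and 165 lower. Cldn7, Cthrc1 (24.3 and 131 CPM), Cnih2, Rab25 and Fgf8 led the higher genes, and Eprn, Jam2, Nr0b1 (310 and 46.5 CPM), Tcl1 and Atp1a4 the lower ones. From 36 to 48 h 47 genes were higher and 92 lower. Cldn7 (19.4 and 73.0 CPM), Prxl2a, Ddah1, Fbp1 and Dpysl2 led the higher genes, and H2-M5, Mymx, Sult6b1, Vwa3b and Trap1a (315 and 75.2 CPM) the lower ones. These counts moved with the CPM floor and the pseudocount, to 192 genes higher at 48 h than at 24 h with a floor of 20 and 559 with a floor of 5.

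**Figure D1:**
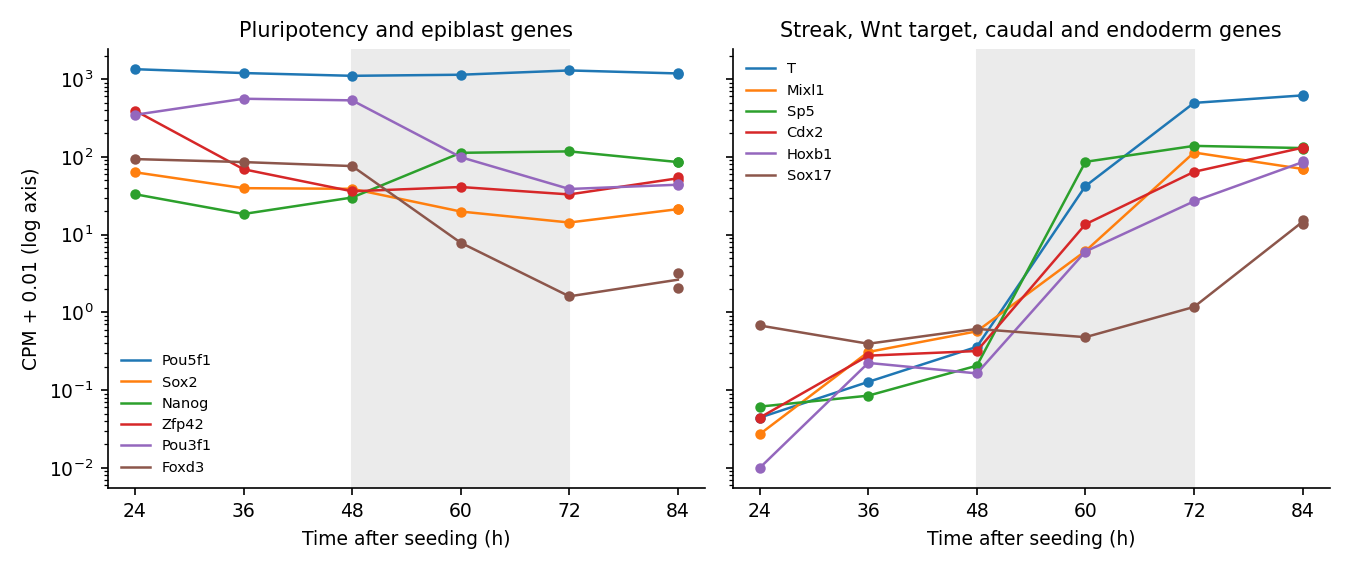
CPM on a log axis against hours after seeding for pluripotency and epiblast genes and for streak, Wnt target, caudal and endoderm genes. Points are libraries, lines join the mean of each time, and grey marks the pulse from 48 to 72 h. T stood at 0.351 CPM at 48 h, 42.1 at 60 h and 494 at 72 h, while Pou5f1 stayed between 1102 and 1341 CPM at all times.

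Across the pulse, from 48 to 72 h, most measured primitive streak, caudal and Wnt target genes were higher, and most measured primed epiblast genes were lower. All 8 measured primitive streak genes were higher at 72 h, with a median log2 ratio of 3.95. T, the gene of the Brachyury reporter, was at 0.351 CPM (exact Poisson interval 0.227 to 0.517) at 48 h, 42.1 (40.3 to 43.9) at 60 h and 494 (489 to 500) at 72 h. The mesendoderm gene Mixl1 was at 0.561 and 114 CPM at 48 and 72 h, Evx1 at 0.168 and 30.0, and the organizer gene Gsc at 0.771 and 31.3. All 6 measured caudal epiblast and neuromesodermal genes were higher, with a median of 4.35, among them the posterior homeobox genes Cdx1 and Cdx2 (0.308 and 64.2 CPM) and Hoxb1 (0.154 and 26.8). Both medians lay above the matched lists.

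Of 8 Wnt targets 6 were higher at 72 h, with a median of 2.07: Sp5 was at 0.196 CPM at 48 h and 138 at 72 h, and the feedback inhibitors Axin2, Dkk1 and Nkd1 were at 4.95 and 71.1, 0.925 and 16.6, and 3.14 and 25.9. Nodal targets were higher in 3 of 7 members, among them Nodal (69.5 and 172 CPM) and Lefty1 (115 and 243), with a median of 0.87. Anterior Hox genes were higher in 3 of 3, among them Hoxb1 and Hoxb2, with a median of 4.13. Of 5 mesenchymal genes 3 were higher, Snai1, a repressor of epithelial genes (4.35 and 21.4 CPM), the cadherin Cdh2 and Twist1, with a median of 1.26. Presomitic mesoderm genes had 2 of 4 higher, Rspo3 and Pcdh8, and Dll1 lower, with a median of 1.64, and definitive endoderm genes had 2 of 4 higher, Foxa2 and Trh, and Krt7 lower. The definitive endoderm list had a median of 1.29, and it and the other lists of this paragraph lay above the matched lists. Its members Sox17, Cer1, Cxcr4 and Foxa1 were below the CPM floor at both times. Trh was far higher in cells annotated Epiblast than in Anterior Primitive Streak at 72 h, as given below, so its rise is not read as one of endoderm.

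Primed epiblast genes were lower in 8 of 12 members, with a median of −1.68. Foxd3 was at 76.1 CPM at 48 h and 1.60 at 72 h, Pou3f1, also called Oct6, at 533 and 38.6, Car4 at 32.0 and 2.78, and the anterior homeobox gene Otx2 at 123 and 27.0. Of 10 shared pluripotency genes 4 were lower, Utf1 (778 and 137 CPM), Dppa2, Dppa4 and Sox2 (38.8 and 14.3), with a median of −0.41. Of 8 naive pluripotency genes Tfcp2l1, Nanog and Tbx3 were higher and Nr0b1 lower, with a median of 0.64. Nanog was at 30.0 CPM at 48 h, 113 at 60 h and 118 at 72 h. Other genes with the largest higher ratios were Foxb1, Alox15, Evx1os and the Sprr2a copies, and other genes with the largest lower ratios were Calml4, Il10, Spp1, Mt3, Wt1, Gtsf1, Irs4, Tstd1, Doc2a and Tsx.

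Signalling and stress lists differed between 48 and 72 h as well. Dissociation and immediate early genes were higher in 4 of 7, Junb (6.45 and 42.5 CPM), Fos (10.0 and 63.1), Jun and Zfp36, with a median of 1.02. FGF and ERK targets had 2 of 9 higher, Spred1 and Egr1 (25.2 and 102 CPM), with a median of 0.53. Notch pathway genes had Nrarp and Hes1 higher and Dll1 lower among 4, with a median of 1.05, and integrated stress response genes had Atf3 and Ddit4 higher among 8, with a median of 0.45. Of 3 extraembryonic endoderm genes Sparc was lower, against a list median of 0.66. All of these medians lay above the matched lists. Below them lay epithelial genes (Krt18 lower among 8, median −0.38), cholesterol synthesis (Fdft1 lower among 12, −0.41), S phase (0 of 10, −0.23) and G2/M phase (0 of 10, −0.25).

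Within the matched range from 48 to 72 h lay BMP targets (Id1 higher among 5, median 0.13), the retinoic acid pathway (1 higher and 1 lower among 3, the lower being Crabp2, −0.30), glycolysis and hypoxia (Slc2a3 higher and Slc2a1 lower among 11, 0.09), p53 targets (Cdkn1a higher at 161 and 579 CPM among 10, −0.09) and primordial germ cell genes (Tfap2c higher and Dazl lower among 3, 0.59). Among lists with fewer than 3 measured genes, Snai1 was higher of 2 nascent and cardiac mesoderm genes and Lmo2 of 1 endothelial and blood gene. Nes was higher and Sox3 lower of 2 neural ectoderm genes, and 0 of 1 fibroblast gene passed. Sox1, the other reporter gene, had at most 0.463 CPM in any library, the value at 24 h.

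By the size rule 407 of 8079 measured genes were higher and 388 lower at 72 h than at 48 h. From 48 to 60 h 188 genes were higher and 240 lower, and Sp5 (0.196 and 86.3 CPM), T, Foxb1, Cdx2 and Eomes, a T-box gene of mesendoderm (4.48 and 58.3), led the higher genes. Foxd3, Irs4, Il10, Wt1 and Btbd17 led the lower ones. For this step the median log2 ratio of all measured genes was 0.06, against −0.05 with TMM scaling. From 60 to 72 h 98 genes were higher and 84 lower, led by Sprr2a1 and Sprr2a2, Mixl1 (6.13 and 114 CPM), T and Alox15, and by Calml4, Smc1b, Nupr1 (174 and 40.9 CPM), Pdzrn4 and Fkbp6. With a CPM floor of 20, 256 genes were higher and 251 lower from 48 to 72 h, and 121 and 157 from 48 to 60 h. With a pseudocount of 5, 55 were higher and 54 lower from 60 to 72 h.

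**Figure D2:**
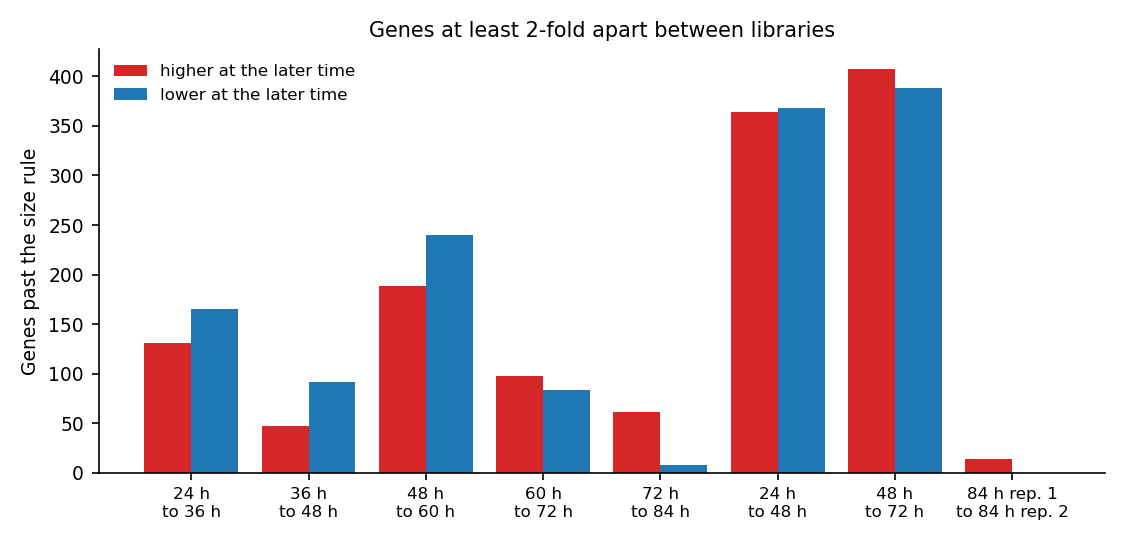
Number of genes past the size rule, higher or lower at the later time, for each comparison and between the 84 h libraries. The 12 h step from 48 to 60 h held the most genes of the 12 h steps, 188 higher and 240 lower, and the 84 h libraries differed in 14 genes.

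After the pulse, from 72 to 84 h, few genes passed the size rule, and most of these were higher at 84 h. Of 7927 measured genes 61 were higher and 8 lower. The 84 h values below are means ± SD of n = 2 libraries. Caudal epiblast and neuromesodermal genes were higher in 3 of 7 members, with a median of 0.49: Hoxb1 was at 26.8 CPM at 72 h and 85.6 ± 3.45 at 84 h, and Cdx2 at 64.2 and 131 ± 0.223. Anterior Hox genes were higher in 3 of 3, with a median of 1.42. Of 4 presomitic mesoderm genes Hes7, a gene of the somite clock (1.78 and 14.3 ± 0.346 CPM), and Rspo3 (16.0 and 45.7 ± 0.205) were higher, with a median of 1.05. The keratins Krt8 (40.5 CPM, then 129 and 131 in the 84 h libraries) and Krt18 were the 2 of 8 epithelial genes past the rule, with a median of 0.22. These medians lay above the matched lists.

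Sox17 and Lhx1 were also among the higher genes at 84 h. Sox17, a regulator of endoderm, was at 1.17 CPM at 72 h and 14.6 ± 1.04 at 84 h and was the 1 of 4 definitive endoderm genes past the rule, with a median of 0.27 within the matched range. Of 9 primitive streak genes Lhx1 was higher (4.83 and 25.0 ± 1.65 CPM) and Eomes lower (59.8 and 24.5 ± 0.958), with a median of −0.19 below the matched lists. Both of the 2 measured primordial germ cell genes were higher, Dnd1 (31.0 and 110 ± 5.87 CPM) and Tfap2c. The Sprr2a genes of the cornified envelope had the largest ratios, Sprr2a1 at 20.9 and 330 ± 20.7 CPM, and other higher genes with large ratios were Psmb8, Ptgs1, H2-Bl and Hotairm1. Lower genes were Egr1, an immediate early gene (102 and 27.8 ± 0.0931 CPM), Tgfbr3, Pdzrn4, Npl, Plpp4, Fabp3, Eomes and Crym. T was at 494 CPM at 72 h and 617 ± 10.1 at 84 h, Sox2 at 14.3 and 21.2 ± 0.143, and Pou5f1 at 1292 at 72 h and 1180 and 1184 in the 84 h libraries. Nanog was at 118 CPM at 72 h and 85.7 ± 0.196 at 84 h.

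No member of other lists passed from 72 to 84 h except Egr1 among 9 FGF and ERK targets, whose median was 0.00. Medians above the matched lists with 0 members past the rule were those of naive pluripotency (7 measured, 0.38), Nodal targets (7, 0.22), BMP targets (4, 0.34), mesenchymal genes (5, 0.34) and glycolysis and hypoxia (11, 0.16). Below the matched lists were p53 targets (10, −0.20), dissociation and immediate early genes (8, −0.21) and the Notch pathway (3, −0.34). Within the range were shared pluripotency (10, 0.05), primed epiblast (10, −0.07), extraembryonic endoderm (3, −0.13), Wnt targets (9, −0.06), the retinoic acid pathway (3, 0.33), cholesterol synthesis (12, 0.00), integrated stress response (8, 0.02), S phase (10, −0.09) and G2/M phase (10, 0.05). The lists of nascent and cardiac mesoderm (2 measured), neural ectoderm (2), endothelial and blood (1) and fibroblast (0) had no median. With a CPM floor of 20 or a pseudocount of 5 the counts were 40 higher and 4 lower.

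T transcripts spread from rare cells to most cells during the pulse. After thinning to 5000 spliced UMIs, 0.0474% of cells held a T UMI at 24 h (95% interval 0.00574 to 0.171), 0.0976% at 36 h, 0.211% (0.105 to 0.377) at 48 h, 17.2% (16.1 to 18.3) at 60 h and 77.2% (76.0 to 78.4) at 72 h. At 84 h the share was 81.6% ± 0.637 (SD, n = 2). Without thinning the shares at 48, 60, 72 and 84 h were 0.454%, 30.9%, 89.8% and 88.7%, so the order of 72 and 84 h depended on depth and is not read here. Thinning left out 174, 377, 67, 122 and 26 cells from 24 to 72 h and 69 and 147 cells at 84 h. Of 29 cells annotated ExE ectoderm at 84 h, taken as a type that should lack T, 13.8% (3.89 to 31.7) held a T UMI, with a median of 7633 UMIs per cell before thinning against 11082 over all cells.

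Other markers followed different courses over the same thinned cells. Pou5f1 was seen in 93.4% to 96.2% of cells from 24 to 72 h and in 90.9% ± 0.692 at 84 h. Sox2 was seen in 25.1% of cells at 24 h, 13.9% at 48 h, 4.50% at 72 h and 6.13% ± 0.401 at 84 h, and Nanog in 13.9%, 13.8%, 42.6% and 32.0% at 24, 48 and 72 h and in 84 h replicate 2. The mesendoderm gene Eomes was seen in 2.16% of cells at 48 h, 22.0% at 60 h, 21.4% at 72 h and 9.66% and 9.69% in the 84 h libraries, and Mixl1 in 0.211%, 2.72% and 26.9% at 48, 60 and 72 h and 21.3% ± 0.222 at 84 h. Tbx6, a gene of paraxial mesoderm, was seen in 0.213% of cells at 72 h and 1.24% ± 0.160 at 84 h. Zfp42, added to these genes after seeing the data, was seen in 75.2% of cells at 24 h, 25.5% at 36 h and 14.9% at 48 h. Later it was seen in 11.9% at 72 h and in 13.9% and 11.6% in the 84 h libraries. Without thinning, Eomes was seen in 5.48% and 16.2% at 48 and 84 h, and Pou5f1 in 94.4% at 24 h. Zfp42 was then seen in 32.85% at 48 h, and Nanog, Mixl1 and Sox2 in 72.1%, 41.4% and 9.15% at 72 h. The shares of all but Pou5f1 thus depend strongly on depth. Of the entries of Sox1 97.2% were fractions that rounding mostly set to 0, so its shares are not read here. Of those of Sox2 64.2% were fractions, and with fractions rounded at random Sox2 was seen in 25.9%, 17.5% and 6.71% of cells at 24, 48 and 72 h and 9.05% ± 0.316 at 84 h. At 72 and 84 h, over all cells of a library, T and Sox2 were in the same cell less often than their shares would give. The expected counts pooled the annotated types, which differed in both genes. At 72 h T was seen in 39.2% and Sox2 in 13.9% of Epiblast cells, against 83.7% and 2.96% of Primitive Streak cells. A mix of types can lower the count of such cells, so whether the genes kept apart within a type was not tested. The ratio of observed to expected cells was 0.694 (0.572 to 0.834) at 72 h and 0.576 (0.460 to 0.712) and 0.646 (0.544 to 0.762) in the 84 h libraries. Rounded at random it was 0.778 (0.671 to 0.897), 0.751 (0.644 to 0.871) and 0.784 (0.687 to 0.891). At 60 h it was 0.684 (0.465 to 0.971) but 0.923 (0.714 to 1.17) when rounded at random, and is not read here.

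**Figure D3:**
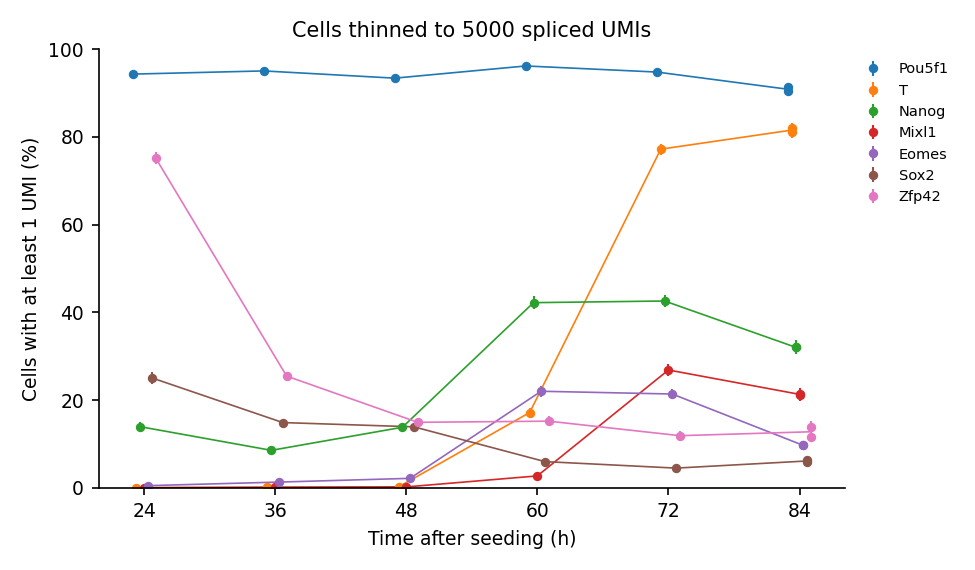
Percent of cells with at least 1 UMI of each gene after thinning every cell to 5000 spliced UMIs, against hours after seeding. Points are libraries with exact 95% intervals, and lines join the mean of each time. The shares of Sox2 depend on how fractions were rounded. T was seen in 17.2% of cells at 60 h and 77.2% at 72 h, and Zfp42 in 75.2% at 24 h and 14.9% at 48 h.

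The cell type names that the authors' annotation gave to cells differed between times. At 24, 36 and 48 h 99.7%, 99.9% and 99.8% of cells were annotated Epiblast. At 60 h 60.3% were annotated Epiblast and 38.7% (37.3 to 40.2) Primitive Streak, the site where mesoderm and endoderm form in the embryo. At 72 h Primitive Streak held 74.2% (72.9 to 75.4) and Epiblast 13.9%, and at 84 h they held 42.5% ± 1.26 and 16.1% of cells in each library. Caudal epiblast stood at 5.79% at 72 h and 15.7% ± 0.324 at 84 h, Anterior Primitive Streak at 3.20% and 7.45% ± 0.323, PGC at 0.212% and 7.35% ± 0.362, and Caudal Mesoderm at 0.318% and 6.77% ± 0.201. Nascent mesoderm was at 0.551% and 1.33% ± 0.0604, and Def. endoderm was at 0.519% ± 0.0232 at 84 h. The summed streak and mesodermal class held 0.0228%, 0.0133% and 0 of 5288 cells at 24, 36 and 48 h, then 38.7%, 84.0% (83.0 to 85.1) and 74.0% ± 0.412 at 60, 72 and 84 h.

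The names at 60 h depended on how cells were classed. When clusters named by the fixed markers replaced the annotation, the streak and mesodermal class held 1.92% at 60 h, 73.1% at 72 h and 80.2% at 84 h, so the order of 72 and 84 h turned too. The annotated class left out the name PGC, which held 0.212% of cells at 72 h and 7.35% at 84 h. With this name added 72 h would still lie above 84 h, since 7.35% is less than the gap between 84.0% and 74.0%. Leaving it out therefore cannot alone account for the turned order, and what else had a part was not tested. The low share at 60 h came with a cluster of 6818 cells in which 2 streak and 4 pluripotency markers were above the other cells. It was not named under a minimum of 3 markers that was set after seeing the data, and it held 25 cells at 48 h, 4370 at 60 h, 1179 at 72 h and 583 and 660 at 84 h. T was seen after thinning in 24.0% (22.0 to 26.1) of the 60 h cells annotated Primitive Streak and in 12.8% (11.6 to 14.2) of those annotated Epiblast.

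**Figure D4:**
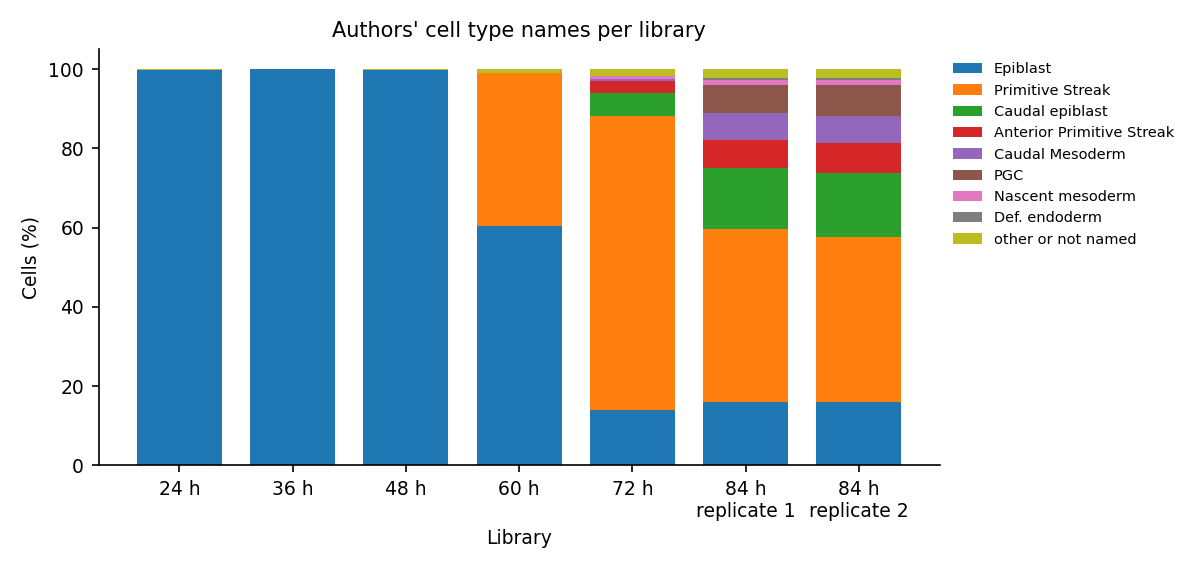
Percent of each library's cells under each of the authors' cell type names, with rare names and cells without a name pooled. Bars add up to 100% per library. Epiblast held 99.8% of cells at 48 h and 13.9% at 72 h, and the 84 h libraries had similar bars, with Primitive Streak at 43.4% and 41.7%.

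At 84 h the annotated types differed in known lineage genes, given as CPM of the summed UMIs of each type, mean ± SD of n = 2 libraries. The organizer gene Gsc was at 360 ± 16.0 in Anterior Primitive Streak and 9.38 ± 0.842 in Primitive Streak, and Lhx1 at 249 ± 10.6 and 4.50 ± 0.239. Sox17 was at 438 ± 65.5 in Def. endoderm, 162 ± 16.1 in Anterior Primitive Streak and 1.91 ± 0.362 in Primitive Streak. Mesp1, an early mesoderm regulator, was at 180 ± 15.6 in Nascent mesoderm and 7.91 ± 1.31 in Caudal Mesoderm. Hes7 was at 71.5 ± 0.613 in Caudal Mesoderm, 33.2 ± 1.54 in Caudal epiblast and 5.22 ± 0.231 in Primitive Streak, and Hoxb1 at 231 ± 2.71, 146 ± 5.56 and 67.9 ± 6.12. Otx2 was at 152 ± 3.38 in Anterior Primitive Streak and 80.5 ± 4.65 in Epiblast, against 2.68 ± 1.11 in Caudal epiblast. T was at 180 ± 23.0 in Epiblast, 665 ± 3.09 in Primitive Streak, 891 ± 43.8 in Caudal Mesoderm and 900 ± 45.75 in PGC. The share of thinned cells with a T UMI was 33.9% and 38.6% in Epiblast and 98.0% and 97.5% in Caudal Mesoderm. The ExE ectoderm background was 13.8% (3.89 to 31.7) over only 29 cells, with an upper bound near the Epiblast shares. Because the names rest on expression, genes that mark a type may have been used to name it.

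**Figure D5:**
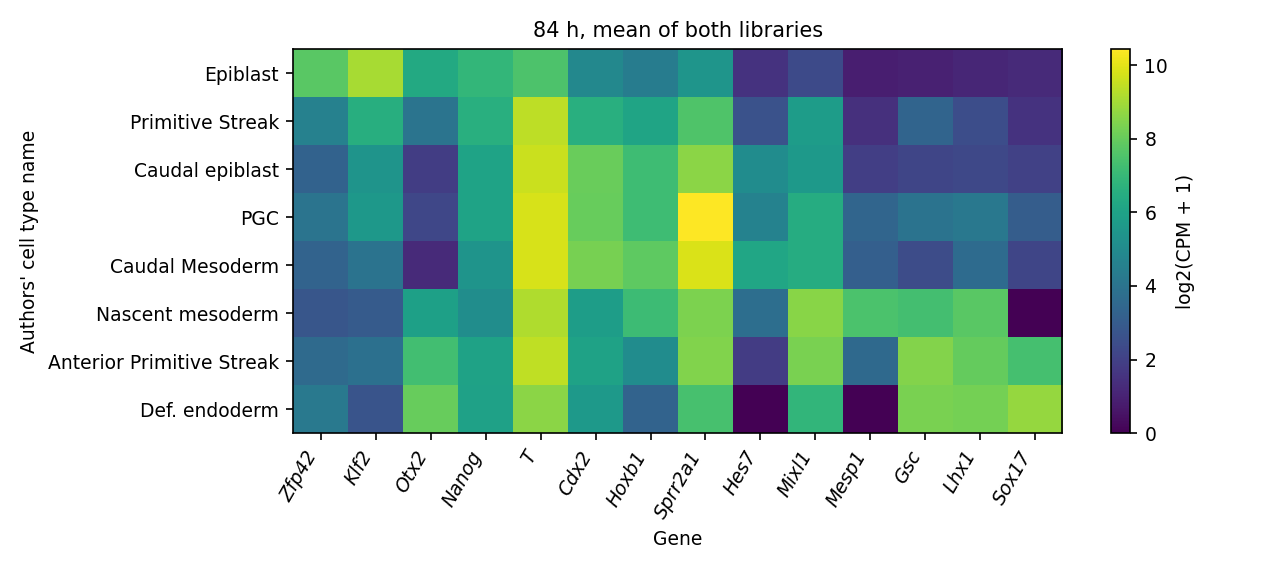
log2 of CPM plus 1 of selected genes in each annotated cell type at 84 h, as the mean of both libraries. Rows are types and columns are genes. Gsc, Lhx1 and Sox17 were high in Anterior Primitive Streak and Def. endoderm, Hes7 in Caudal Mesoderm, and Klf2 and Zfp42 in Epiblast.

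Within the cells annotated Epiblast, naive pluripotency genes were higher and primed genes lower at 84 h than at 48 h. Much of this was present at 72 h. From 48 to 72 h 6 of 8 measured naive genes were higher, with a median log2 ratio of 1.70, and 9 of 12 primed genes lower, with −1.565. From 72 to 84 h 1 of 11 naive genes was higher, with a median of 0.63, and 0 of 9 primed genes passed. From 48 to 84 h, of 11 measured naive pluripotency genes 9 were higher and 0 lower, with a median log2 ratio of 1.96 above the matched lists. Klf2 was at 61.7 CPM at 48 h and 541 and 533 in the 84 h libraries, Zfp42 at 36.0 and then 223 and 206, Tfcp2l1 at 2.05 and then 25.2 and 26.4, and Nanog at 30.0 and then 111 and 129. Primed epiblast genes were lower in 8 of 12, with a median of −1.65, and Pou3f1 was at 533 CPM and then 79.1 and 71.8. T was at 0.351 CPM and then 164 and 197. The gene Tfap2c, active in germ cell precursors and in surface ectoderm, was at 1.64 CPM and then 71.9 and 68.5. In all, 275 genes were higher and 222 lower in these cells at 84 h than at 48 h, against 11 and 5 between the 84 h libraries. Different clusters held most of the class at these times: clusters 2 and 4, with 59.6% and 38.4% of it at 48 h, and cluster 3, with 73.8% and 65.1% of it in the 84 h libraries. Cluster 1, which the fixed markers named streak or mesodermal, held another 21.1% and 29.2% of it in these libraries. The 84 h values of the class are therefore those of a mixture by these clusters.

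Differences between times were also seen inside annotated types. Among Epiblast cells 362 genes were higher and 367 lower at 48 h than at 24 h, of which 361 and 367 also passed over all cells. From 48 to 72 h 320 were higher and 255 lower in these cells, with 235 and 219 shared with the comparison over all cells. From 72 to 84 h the counts were 27 and 19 in Epiblast, 40 and 12 in Primitive Streak, 61 and 30 in Caudal epiblast and 199 and 43 in Anterior Primitive Streak. Between the 84 h libraries they were 11 and 5, 7 and 0, 24 and 1, and 30 and 13 in the same order of types. The counts of Caudal epiblast and Anterior Primitive Streak rest on 273 and 151 cells at 72 h.

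Unspliced transcripts, which mark recent transcription, were a larger part of UMIs from 60 h on. The unspliced share was 17.2%, 17.1% and 17.5% at 24, 36 and 48 h, then 19.1% and 19.3% at 60 and 72 h and 19.2% ± 0.0328 at 84 h. Genes were compared only with at least 1 spliced CPM beforehand and 100 unspliced UMIs over all libraries, without predicted, mitochondrial and ribosomal protein genes. Of the genes higher at the next time this used 85 of 131, 35 of 47, 133 of 188, 72 of 98 and 33 of 61. It left out T and Sp5 at 48 h. The genes used did not have more unspliced relative to spliced UMIs beforehand than matched random lists. The median of their log2 ratios lay at percentiles 11.6, 2.44, 53.4, 1.99 and 0.87 of the matched lists for the steps beginning at 24, 36, 48, 60 and 72 h. The steps beginning at 36, 60 and 72 h thus lay below the matched lists. For genes lower at the next time the percentiles were 20.7, 15.8, 9.34, 0.01 and 88.7, the last over 6 genes. Random lists were matched on spliced CPM only, and not on a gene's own ratio at other times. Some genes have a low ratio at every time, as Sox2 had 0 unspliced UMIs in all libraries. The comparison therefore cannot show whether unspliced transcripts ran ahead of a later rise.

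Genome positions of the reporter and pluripotency genes are given on GRCm38, all as protein-coding genes on the forward strand. T (ENSMUSG00000062327.10) lies on chromosome 17 from 8434423 to 8442496 and Pou5f1 (ENSMUSG00000024406.16) on chromosome 17 from 35506018 to 35510772. Sox2 (ENSMUSG00000074637.7) lies on chromosome 3 from 34650405 to 34652461, Sox1 (ENSMUSG00000096014.1) on chromosome 8 from 12395295 to 12400126, and Nanog (ENSMUSG00000012396.12) on chromosome 6 from 122707489 to 122714633.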

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

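The tests for free RNA and for a general increase of ribosomal protein RNA were chosen only after the results they measure were seen, and the test over the whole naive list was added after the result for Zfp42 was seen.

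From 72 to 84 h, 2 genes moved in opposite directions in different annotated cell types, in both 84 h libraries, and this difference was not tested. Cldn6, a tight junction gene, had a log2 ratio of 1.12 in Anterior Primitive Streak (50.9 CPM at 72 h and 112 ± 5.99 at 84 h) and −1.16 in Caudal epiblast (43.1 and 18.8 ± 1.58). Trh, a gene of early endoderm, had a log2 ratio of 2.62 in Anterior Primitive Streak (56.7 and 355 ± 32.9 CPM) and −1.22 in Caudal epiblast (307 and 133 ± 27.2).

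Naive pluripotency genes were higher at 84 h than at 48 h in cells annotated Epiblast, and 6 of 8 measured members were already higher at 72 h. Scaling was argued against, since the list's median log2 ratio was 1.90 or more in each library with the authors' per-cell factors, and so was free RNA, since the median of Epiblast over Primitive Streak cells of the same library was 1.90 or more. Departure from the class of cells without these transcripts was argued against for Zfp42 at high counts only. There, 2.94% or more of all cells held at least 3 thinned Zfp42 UMIs at 84 h, above the 48 h bound of 0.729%. At 1 UMI or more the share of all cells was 14.9% at 48 h and 13.9% and 11.6% in the 84 h libraries, so departure stays open there. Over the list departure cannot be told apart from higher expression, because 7 of 11 members had more cells at high counts, fewer than the 8 set as the bound, and Klf4, Klf5, Nr0b1 and Dppa3 did not. Time in culture and the CHIR99021 pulse from 48 to 72 h, which the design does not separate here, stay open and were not tested.

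Cells annotated PGC at 84 h were weighed for a first impression that they held few germ cell genes. The measured germ cell genes, 3 of 6, had a median log2 ratio over other cells of 1.33 and 1.46 in the 84 h libraries, above all matched random lists, but names that rest on expression can give this by construction, so it does not decide on that impression. These cells held 0.845 times the library's median of spliced UMIs or more, which argued against shallow cells as a cause of few such genes. Between PGC and Caudal Mesoderm 80 genes or more differed within a library, against 38 between the libraries within PGC and under the bound of 3 times as many, and 15 genes were higher and 10 lower in both libraries. Whether these were separate populations stayed open, since names that rest on expression would also divide 1 graded population by such genes, and no biological explanation was tested.

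Copies of ribosomal protein genes differed between the 84 h libraries. An increase of 2-fold or more in replicate 2 across the measured ribosomal protein genes and copies was argued against, since their median log2 ratio was 0.0845 over 49. Only 4 of 80 protein-coding ribosomal protein genes had a row, so ribosomal protein RNA of every kind was not measured, and a smaller increase was not weighed. UMIs shared with near-identical copies stay open: the median percent of fractional entries over the 14 genes was 65.1%, against a 95th percentile of measured genes of 71.2%. No biological explanation was tested, and the labels name no difference between these libraries.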

How the results depend on the processing

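The authors' per-cell factors, removal of the 5% highest Scrublet scores, clusters in place of the annotation and rounding of fractions at random were chosen only after seeing the data. No paired analysis was possible because only 84 h has more than 1 library, so the groups share fewer than 2 replicate numbers. Of 164 counts of genes under the alternatives, 136 stayed within 1.5 times the main count, 21 were smaller and 7 larger. List medians and log2 ratios of named genes were held to 1 limit, a move of 0.0978 from the main value. This was the SD of the genes' log2 ratios between the 84 h libraries and not a spread of each result. Of 591 list medians 543 stayed within it, 47 moved further and 1 reversed. Of 2632 log2 ratios of named genes 2360 stayed, 272 moved and 0 reversed. Depth limits genes of low CPM, as 10 CPM stood for 381 to 935 UMIs per library.

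With a CPM floor of 20, higher genes numbered 62 from 24 to 36 h, 21 from 36 to 48 h (55 lower), 121 from 48 to 60 h (157 lower), 40 from 72 to 84 h (4 lower), 192 from 24 to 48 h, 256 from 48 to 72 h (251 lower) and 8 between the 84 h libraries. With a floor of 5 they numbered 206 from 24 to 36 h, 82 from 36 to 48 h, 97 from 72 to 84 h and 559 from 24 to 48 h, and 3 genes were lower between the 84 h libraries. With a pseudocount of 5, 65 were higher and 104 lower from 24 to 36 h, 15 and 49 from 36 to 48 h, 55 and 54 from 60 to 72 h and 40 and 4 from 72 to 84 h, with 239 higher from 24 to 48 h and 9 between the 84 h libraries. A floor sets how many genes are measured and a pseudocount shrinks the ratios of genes with low CPM. With the mean of each cell's CPM, and with the authors' factors, 2 genes were lower between the 84 h libraries, and the cause was not tested. Leaving out an 84 h library gave 66 to 82 genes higher and 9 to 11 lower from 72 to 84 h. The median of dissociation and immediate early genes from 24 to 48 h reversed to −0.21 with spliced plus unspliced UMIs, and the cause was not tested.

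Thinned to 2500 UMIs, the share of cells with a T UMI was 0% at 24 h, 0.0265% at 36 h, 9.26% at 60 h, 61.8% at 72 h and 69.3% at 84 h. Thinned to 10000 UMIs it was 0.420% at 48 h, 30.4% at 60 h, 88.5% at 72 h and 85.4% at 84 h, and without thinning 0.454%, 30.9%, 89.8% and 88.7%. More UMIs per cell give more chances to see T by construction. Without the 5% highest Scrublet scores the 84 h share was 80.9%, and leaving out a library gave 81.1% to 82.0%. With fractions rounded at random every T share stayed within its spread.

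The streak and mesodermal class at 84 h was 73.3% without the 5% highest Scrublet scores and 73.7% to 74.3% when a library was left out. With clusters in place of the annotation it was 1.92%, 73.1% and 80.2% at 60, 72 and 84 h. With resolution 0.5 it was 2.65%, 75.7% and 82.4%, with resolution 2 3.81%, 72.9% and 81.7%, with 50 principal components 3.02%, 78.3% and 82.9%, and with 4000 variable genes 2.01%, 71.0% and 81.4%. Clusters gave most 60 h cells to 1 or more clusters without a name, and why the annotation split these cells was not tested.

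The unspliced share, in order of time, was 17.2%, 17.1%, 17.5%, 19.0%, 19.3% and 19.2% with the stricter filter, and 17.4%, 17.3%, 17.6%, 19.1%, 19.4% and 19.4% as a mean of cells. Without the 5% highest Scrublet scores it was 17.1% at 36 h and 19.4% at 72 h. These moves were small but past the narrow counting intervals, and the cause was not tested.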

Other observations

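All values in this part were chosen after seeing the data.

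Cells annotated PGC and Caudal Mesoderm at 84 h differed in known lineage genes in both libraries, with 15 genes higher in PGC and 10 lower. Tdgf1, a Nodal co-receptor of pluripotent cells, was at 276 and 290 CPM in PGC and at 82.6 and 80.0 in Caudal Mesoderm of replicates 1 and 2. The germ cell gene Nanos3 was at 13.8 and 16.8 against 3.90 and 4.89, and Klf2 at 40.6 and 52.6 against 12.3 and 16.7. These 3 genes were not particular to PGC, as cells annotated Epiblast held Tdgf1 at 513 and 525, Nanos3 at 13.6 and 13.8 and Klf2 at 541 and 533. The Hox genes Hoxb4 and Hoxb8 were lower in PGC, Hoxb4 at 5.62 and 5.17 against 27.1 and 30.0, and the clock gene Hes7 was at 28.1 and 19.4 against 71.9 and 71.0.

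Trh was high in cells annotated Epiblast from 60 h on, at 173 CPM at 48 h, 1164 at 60 h, 1179 at 72 h and 1224 ± 25.4 at 84 h. Sprr2a1 at 84 h was at 1385 ± 36.4 CPM in PGC, 918 ± 141 in Caudal Mesoderm and 42.8 ± 2.32 in Epiblast, with UMIs that near-identical genes can share.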
